A study of Mus musculus with 18 samples.

How the data were processed

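Gene expression was measured on 18 Affymetrix mouse arrays in NaF cells, a mouse mammary carcinoma line, in 6 groups of 3. Per the labels, the cells of 12 samples were moved from full medium (DMEM with 10% FBS) to DMEM with 10% charcoal-treated FBS, a serum stripped of small lipophilic molecules, 48 hours before ligand treatment. Of these, 3 were controls and 3 each received all-trans retinoic acid, TTNPB or GW1516 at 1 µM for 6 hours. The other 6 samples stayed in full medium, 3 as controls and 3 with palmitate at 10 µM for 6 hours. RNA was extracted with Qiazol, cleaned on RNeasy columns and labelled as biotinylated cRNA with the Affymetrix IVT protocol.

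The values are the log2 values deposited by the authors, 1 per probe set and array, for 41345 probe sets. The submitters' processing notes name Partek, with a version not given in the sources used here. The method of background correction, normalization and summary is likewise not given in the sources used here. That the scale is log2 was read from the range of the values. The arrays of each serum had a distribution of their own. Medians lay between 1.06 and 1.32 on the 12 charcoal-serum arrays and between 0.47 and 0.55 on the 6 full-medium arrays. The 2 sets of arrays may thus have been scaled apart, so levels in the 2 sets cannot be compared directly. The number of arrays limits the precision, and array values carry no counting depth. The share of probe sets with an identical value (within 1e-06) in a pair of replicate arrays was at most 0.473% in the charcoal set and 2.3% in the full-medium set.

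Of the probe sets, 23521 carried 1 gene symbol, 1814 carried several and 16010 carried none. Symbols were updated by Entrez number for the 23328 probe sets found in a reference table of the GRCm38.p6 assembly. Probe sets with several symbols or none were left out of the comparisons. For the 1082 genes with more than 1 probe set, the one with the highest mean over all arrays was used, which gave 22180 genes. No gene was left out for low signal. Background was taken as the 95th percentile, per group, of the group means of 1394 olfactory and vomeronasal receptor genes, a definition chosen after the data were seen. It came to 1.31 in charcoal controls, 1.15 with retinoic acid, 1.29 with TTNPB, 1.30 with GW1516, 0.59 in full-medium controls and 0.63 with palmitate. Genes at or under it are reported as not measurable.

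Group means were fitted to all 18 arrays with limma 3.58.1 in R 4.3.3, with moderated variances that follow a trend with expression (12 residual degrees of freedom). Contrasts compared each ligand with its control in the same serum, the ligands with one another, the control groups of both sera, and the palmitate effect with the effects of retinoic acid and GW1516. P-values were 2-sided and were adjusted by the Benjamini-Hochberg method over the genes of 1 contrast, with a threshold of 0.05. Fold changes are 2 to the power of the fitted log2 difference. The p-values measure only the spread between these arrays, because the labels do not state whether replicates were separate cultures grown on different days.

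A total of 22 gene lists (16 pathways and 6 cell types, 354 of 398 genes measured) was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of 1 contrast. The tests were repeated with an estimated correlation and with fry, which asks whether the genes of a list move one way on balance. Counts of list members past the threshold are given over all genes tested and adjusted over the list alone. The gene lists, contrasts, list tests and the rule for named genes were chosen before the data were examined. The rule named, per comparison, the 10 largest rises and 10 largest falls past the threshold with all 3 arrays of one group beyond all 3 of the other. It added up to 4 members of each list past the threshold with the largest change (8 for the lists of retinoic acid receptor targets, PPAR targets and retinoid handling). For list members there was no demand on single arrays. Cyp26a1, Rarb, Dhrs3, Crabp2, Fabp5, Ppard, Rara, Pdk4, Angptl4, Plin2 and Pdpk1 were added in every ligand and palmitate comparison. Gene models with only a provisional name were passed over. Genes named outside this rule are marked as chosen after their values were seen.

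The other settings chosen beforehand were a fit on only the groups of a comparison, the replicate number as a block, variances without a trend or with a robust prior, quantile normalization, arrays centred on their medians, array weights, dim genes left out (those with a mean under the median of all probe sets), the mean of all probe sets of a gene, all probe sets tested, a fold of at least 1.5, an adjusted p below 0.01, and each array left out in turn. A fit on arrays of the same serum and a fit without GW1516 replicate 3 and palmitate replicate 2 together were chosen after the data were seen. The code was tested on simulated data with known changes. With equal spread on every array, 5.01% to 5.37% of calls were false over 10 runs. A bound of 15% on false calls was first applied with each array keeping its own spread, and GW1516 missed it. In that setting 27.0% of GW1516 calls were false, against 1.27% for retinoic acid, 1.91% for TTNPB and 0.577% for palmitate. The bound was then kept only for equal spread, and the values with own spread are given without one. With own spread, 93.4% of true log2 changes of 1 were recovered for GW1516 and 45.5% of changes of 0.5.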

Results

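The series examined how ligands of the retinoic acid receptors (RAR) and of PPARδ change gene expression in NaF mouse mammary carcinoma cells. Its title adds saturated fatty acids and the fatty acid-binding protein FABP5. Retinoic acid is the natural RAR ligand, TTNPB is a synthetic RAR agonist, GW1516 is a synthetic PPARδ agonist and palmitate is a saturated fatty acid. Each of the 6 groups had 3 arrays, and values are log2 expression values. Nearly all genes called between a pair of groups had all 3 arrays of one group beyond all 3 of the other. These were 1165 of 1174 genes for retinoic acid, 279 of 279 for TTNPB, 568 of 570 for GW1516, 151 of 151 for palmitate and 20440 of 20741 for the sera. The choice of genes by their p-value makes this nearly certain, so it adds no evidence. Over all genes tested, the arrays separated in either direction for 24.1%, 17.9%, 16.3%, 15.2% and 94.7% in the same order. Positions are on GRCm38.p6.

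GW1516 replicate 3 stood apart from the other arrays. Its values lay 0.231 on average from the mean of its group, against 0.0816 to 0.145 for the other arrays, and the median of its receptor genes, a measure of background, was 0.995 against 0.676 and 0.715 in GW1516 replicates 2 and 1.

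**Figure D1:**
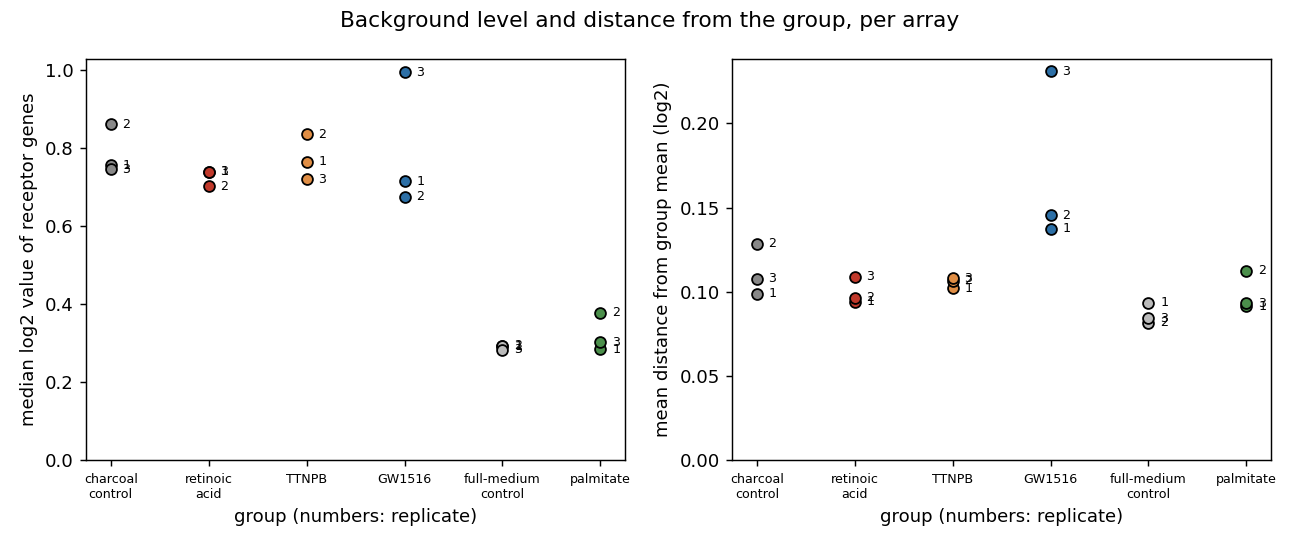
Left, the median log2 value of olfactory and vomeronasal receptor genes on each of the 18 arrays; right, the mean absolute distance of each array from the mean of its group (log2), with replicate numbers beside the points. GW1516 replicate 3 is highest in both panels, at 0.995 and 0.231.

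Retinoic acid raised Cyp26b1, which encodes a retinoic acid-degrading enzyme, 6.15-fold over the charcoal control. The log2 value went from 3.41 ± 0.30 to 6.03 ± 0.19 (SD, n = 3 each), a log2 change of 2.62 ± 0.17 (SE, adjusted p = 4.88e-08). Cyp26b1 (probe set 17468286, Entrez 232174) lies on chromosome 6 from 84571414 to 84593908. Rarb, a receptor gene that is itself a classical RAR target, rose 2.26-fold, by 1.18 ± 0.17 (adjusted p = 0.000448). The nuclear receptor corepressor gene Nrip1 rose 2.62-fold and the transglutaminase gene Tgm2 1.66-fold. Further large rises were those of Ptp4a1 (log2 change 2.38), Atxn7l1 (2.16), Trav12-2 (1.99), Tc2n (1.87) and Trav9d-3 (1.86). The arrestin family gene Arrdc3 (1.71), Hsf2bp (1.70), Postn (1.69) and Ehd3 (1.66) rose as well. Trav12-2 and Trav9d-3, which are T-cell receptor segments, did not keep their calls under every setting chosen beforehand. The largest falls included Rnu3a (log2 change -1.86), Ppp1r10 (-1.46), Snora75 (-1.45), the lipid transporter gene Mfsd2a (-1.44), Klf16 (-1.35) and Nelfa (-1.23).

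Of 19 measured RAR target genes, 5 rose and none fell after retinoic acid (6 rose when adjusted over the list alone), namely Cyp26b1, Nrip1, Rarb, Tgm2 and Plat (log2 change 0.78). The list shifted upward (adjusted p = 0.00477, and adjusted p = 0.0771 with an estimated correlation), with a mean of 0.34 but a median of 0.02. Of other well-known targets, Cyp26a1 and Dhrs3 were under background in both groups, and Crabp2 stood just above it, at 1.28 with retinoic acid and 1.39 in controls, beside backgrounds of 1.15 and 1.31.

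Lipid genes split after retinoic acid. In the list of fatty acid synthesis genes and LXR targets, 5 of 17 rose and 1 fell (7 and 2 when adjusted over the list alone). The cholesterol exporter gene Abca1 rose by 1.36 ± 0.15 (SE), the elongase genes Elovl5 and Elovl6 by 0.72 and 0.58, and the desaturase gene Scd1 by 0.44. The fall was that of the fatty acid synthase gene Fasn (log2 change -0.27, adjusted p = 0.0283). The list shifted upward (adjusted p = 0.000227, and adjusted p = 0.0771 with an estimated correlation). Of 18 cholesterol synthesis genes, 2 fell, both also when adjusted over the list alone: Sqle, which encodes squalene epoxidase (log2 change -0.83), and Fdft1, which encodes squalene synthase (-0.60). That list shifted downward (adjusted p = 0.00341, and adjusted p = 0.307 with an estimated correlation).

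Of 24 cell cycle genes, 8 fell and 1 rose after retinoic acid (13 and 4 when adjusted over the list alone), among them the replication licensing genes Cdc6 (log2 change -0.90) and Mcm5 (-0.49) and the ribonucleotide reductase gene Rrm2 (-0.47), while the topoisomerase gene Top2a rose by 0.72. The list shifted downward (adjusted p = 0.000782, and adjusted p = 0.307 with an estimated correlation). Of 20 genes of apoptosis and growth arrest, 4 rose and 1 fell (5 and 1 when adjusted over the list alone). The cyclin-dependent kinase inhibitor genes Cdkn1b and Cdkn2b rose by 0.70 and 0.46, as did the survival gene Bcl2 (0.95) and Trp53inp1 (0.90). The list's shift was upward by the test (adjusted p = 0.0452, and adjusted p = 0.307 with an estimated correlation), with a mean of 0.17 and a median of -0.03.

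Single members of other lists also moved after retinoic acid. Of 19 ER stress genes 4 rose and 1 fell (5 and 3 when adjusted over the list alone), the rises being those of Ddit3 (log2 change 1.08), Atf3 (0.68), Hsp90b1 (0.60) and Asns (0.47). Of 19 interferon genes 1 rose, also 1 when adjusted over the list alone, Mx1 by 1.38. Of 15 NRF2 and AhR targets 3 rose and 1 fell (3 and 2 when adjusted over the list alone), among them Tiparp (1.23) and the cystine transporter gene Slc7a11 (1.03). Of 19 EMT and TGF-beta targets 2 rose and 1 fell (4 and 1 when adjusted over the list alone), Snai1 by 0.95, and of 23 serum response genes 1 rose and 4 fell (also 1 and 4 when adjusted over the list alone), Spry4 by 0.58 and Myc by 0.54. Fabp5 had a log2 change of -0.15 ± 0.18 (SE, adjusted p = 0.775) and Ppard of 0.42 ± 0.15 (adjusted p = 0.139). Plin2 and Pdpk1, both known as PPARδ targets, had changes of 0.46 (adjusted p = 0.109) and 0.22 (adjusted p = 0.621). Angptl4, another such target, was under background in every group, and Pdk4 stood at 1.18 with retinoic acid, beside a background of 1.15.

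Over all genes, retinoic acid changed 1174 of 22180, with 848 rises and 326 falls. Without single arrays the count ranged from 583 (without retinoic acid replicate 2) to 932, with 627 without retinoic acid replicate 1 and 665 without control replicate 2, and rises made up 72.2% of calls but 54.6% after quantile normalization. Plat lost its call when any 1 of 5 arrays was left out (adjusted p between 0.0658 and 0.213), as did Snai1 for 4 arrays (0.0676 to 0.106) and Myc for 4 (0.0618 to 0.0739), and the list of apoptosis and growth arrest lost its call on the 6 arrays alone (0.129), with a replicate block (0.0547), after quantile normalization (0.217), without dim genes (0.379) and without control replicate 2 (0.113) or retinoic acid replicate 3 (0.0649).

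**Figure D2:**
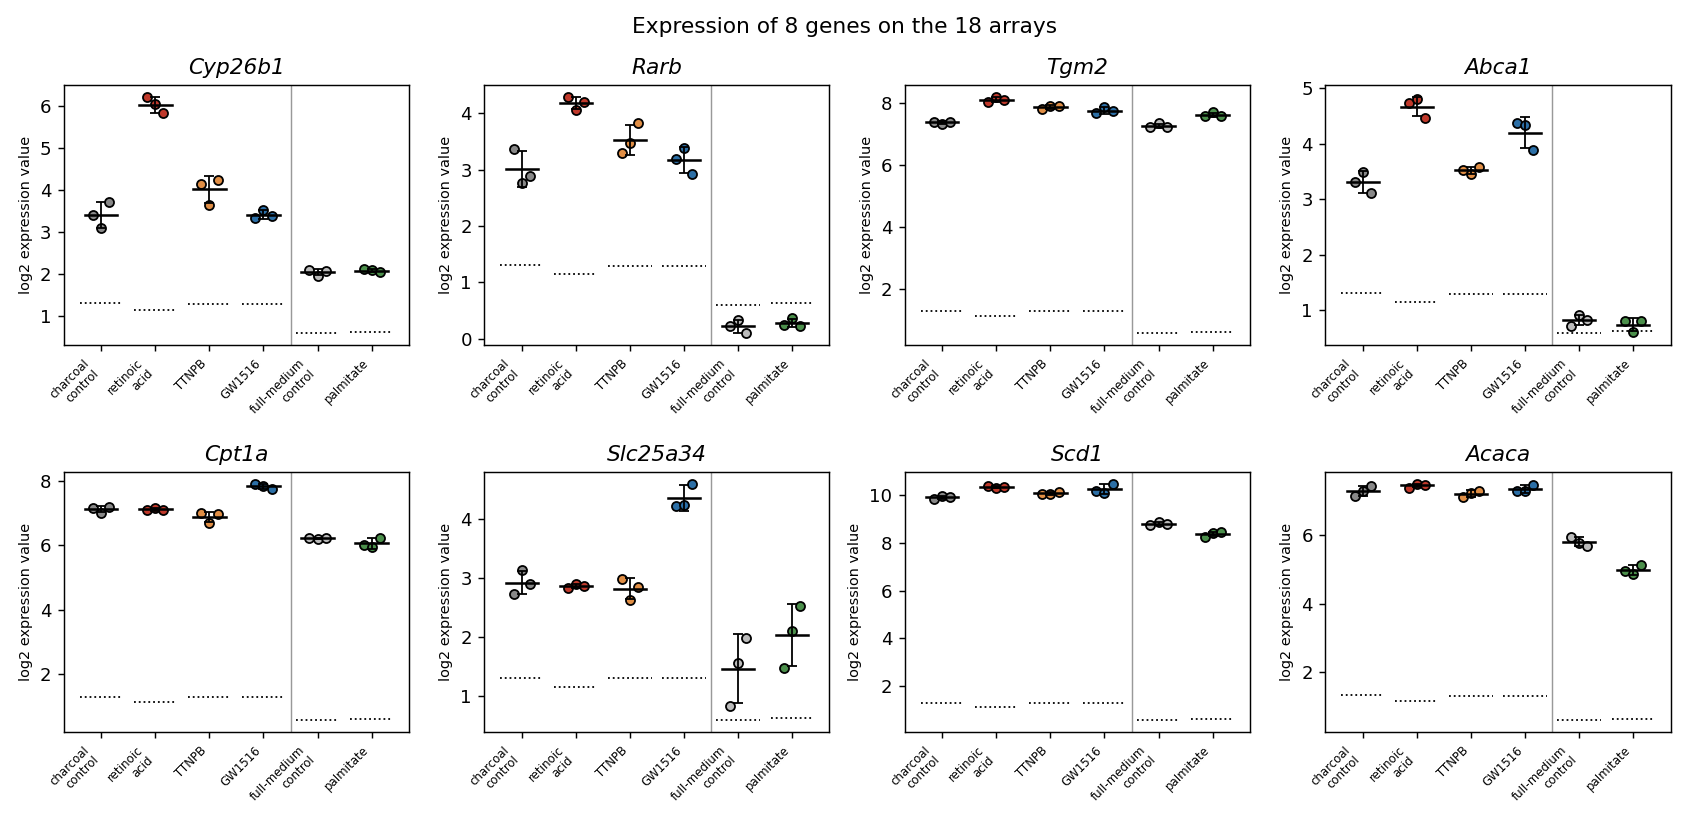
Log2 expression values of 8 genes on the 18 arrays; points are arrays, bars are group means with SD, dotted lines are the background of each group, and the vertical line parts the sera, whose levels cannot be compared. Cyp26b1 rose by 2.62 with retinoic acid, Cpt1a by 0.71 with GW1516, and Acaca fell by 0.83 with palmitate.

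TTNPB, at the same dose and time, raised Atxn7l1 3.27-fold (log2 change 1.71 ± 0.19 SE, adjusted p = 8.42e-05), the transcriptional inhibitor gene Id4 2.71-fold and Arrdc3 2.58-fold. Scarna2, a small RNA of Cajal bodies, rose by 1.07 and the stress gene Ddit3 by 1.12. The largest falls were those of Rnu3a (log2 change -2.04), Ppp1r10 (-1.60), Nelfa, which encodes a subunit of the negative elongation factor (-1.41), Mfsd2a (-1.31), Klf16 (-1.11), Trmt61a (-1.10) and the splicing factor gene Srsf2 (-1.04). Of 19 RAR target genes 1 passed the test (4 when adjusted over the list alone), Tgm2 with a rise of 0.50 ± 0.08. Cyp26b1 changed by 0.60 ± 0.17 (adjusted p = 0.0969), a value outside the naming rule given here because it led the retinoic acid response, and Rarb by 0.52 ± 0.17 (adjusted p = 0.179). The RAR list as a whole did not pass (adjusted p = 0.105), but it did without TTNPB replicate 2 (0.0395) and with fry (0.0442).

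Of the 24 cell cycle genes, 3 fell and none rose with TTNPB (12 and 3 when adjusted over the list alone), namely Cdc6 (log2 change -0.85), Rrm2 (-0.63) and Mcm5 (-0.27). The list shifted downward (adjusted p = 2.51e-05, and adjusted p = 0.202 with an estimated correlation). Of 18 genes of hypoxia and glycolysis, 2 rose (6 when adjusted over the list alone), the collagen prolyl hydroxylase gene P4ha1 by 0.68 and the glycolytic gene Pgk1 by 0.31. That list shifted upward (adjusted p = 0.000368, and adjusted p = 0.0631 with an estimated correlation). Cdkn1b (0.58), Bcl2 (0.60) and Hsp90b1 (0.50) rose, while Id2 (-0.70), the cytokine gene Csf1 (-0.64) and Myc (-0.59) fell. Fabp5 had a log2 change of -0.19 (adjusted p = 0.814).

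TTNPB changed 279 genes, 137 upward and 142 downward. Leaving out any 1 array gave 112 (without TTNPB replicate 1) to 170, that is 122, 157 and 170 without control replicates 1, 2 and 3, and 136 and 131 without TTNPB replicates 2 and 3.

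Retinoic acid and TTNPB differ in that aromatic rings take the place of much of the polyene chain in TTNPB. At the matched dose and time, 34 of 22180 genes differed between them, 24 higher with retinoic acid and 10 higher with TTNPB. Cyp26b1 was 4.05-fold higher with retinoic acid (log2 difference 2.02, 95% interval 1.66 to 2.37, adjusted p = 1.13e-05). Tc2n (1.69), Mx1 (1.28), the Notch ligand gene Jag1 (1.16), Abca1 (1.15), Nrip1 (0.96) and the lipogenic transcription factor gene Srebf1 (0.70) were also higher with retinoic acid. Higher with TTNPB were the small RNA genes Snora75 (log2 difference -1.95), Snord13 (-1.30) and Scarna2 (-0.69), the linker histone gene H1f5 (-0.55), Fdft1 (-0.47) and the translation factor gene Eif4a1 (-0.45).

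Fatty acid synthesis genes and LXR targets as a list were higher with retinoic acid than with TTNPB (2 of 17 members passed, 5 when adjusted over the list alone; adjusted p = 6.48e-06, and adjusted p = 0.0387 with an estimated correlation). Cholesterol synthesis genes were lower, 1 of 18 members on its own (9 when adjusted over the list alone; adjusted p = 1e-06, and adjusted p = 0.0774 with an estimated correlation). RAR targets were higher, 2 of 19 members on their own (4 when adjusted over the list alone; adjusted p = 0.0261, and adjusted p = 0.109 with an estimated correlation).

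Other genes did not differ by the test, and their intervals limit the difference. Rarb differed by 0.65 (interval 0.29 to 1.02, unadjusted p = 0.00131, adjusted p = 0.221), an interval that lies above 0 on its own but does not pass over all genes. For Ddit3 the difference was -0.04 (-0.35 to 0.28), for Mfsd2a -0.13 (-0.40 to 0.14) and for Cdc6 -0.05 (-0.29 to 0.18). Of the 227 genes that both compounds moved in the same direction, 7 differed and 176 had an interval within 1.5-fold of no difference, with a median size of 0.76 for retinoic acid and 0.67 for TTNPB. A choice on calls with both compounds favours like sizes. Of the 1174 genes called with retinoic acid, 678 had such an interval, with medians of 0.64 for retinoic acid and 0.38 for TTNPB. Among these 1174 genes, 1086 had the larger change with retinoic acid, a number raised by their having been chosen on that compound. Of the 279 called with TTNPB, 213 had such an interval, with medians of 0.65 for retinoic acid and 0.63 for TTNPB. The count of 34 fell to 9 without retinoic acid replicate 1, to 13 and 21 without its replicates 2 and 3 and to 16 without TTNPB replicate 2, and after quantile normalization 48.8% of calls, against 70.6% before, were higher with retinoic acid. Nrip1 and the RAR list lost their calls after quantile normalization (adjusted p = 0.111 and 0.0518) and without retinoic acid replicate 1 (0.121 and 0.0683), as did Srebf1 without that array (0.0624) and the RAR list on the 6 arrays alone (0.0795) and without retinoic acid replicate 3 (0.0529) or TTNPB replicate 2 (0.0752).

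**Figure D3:**
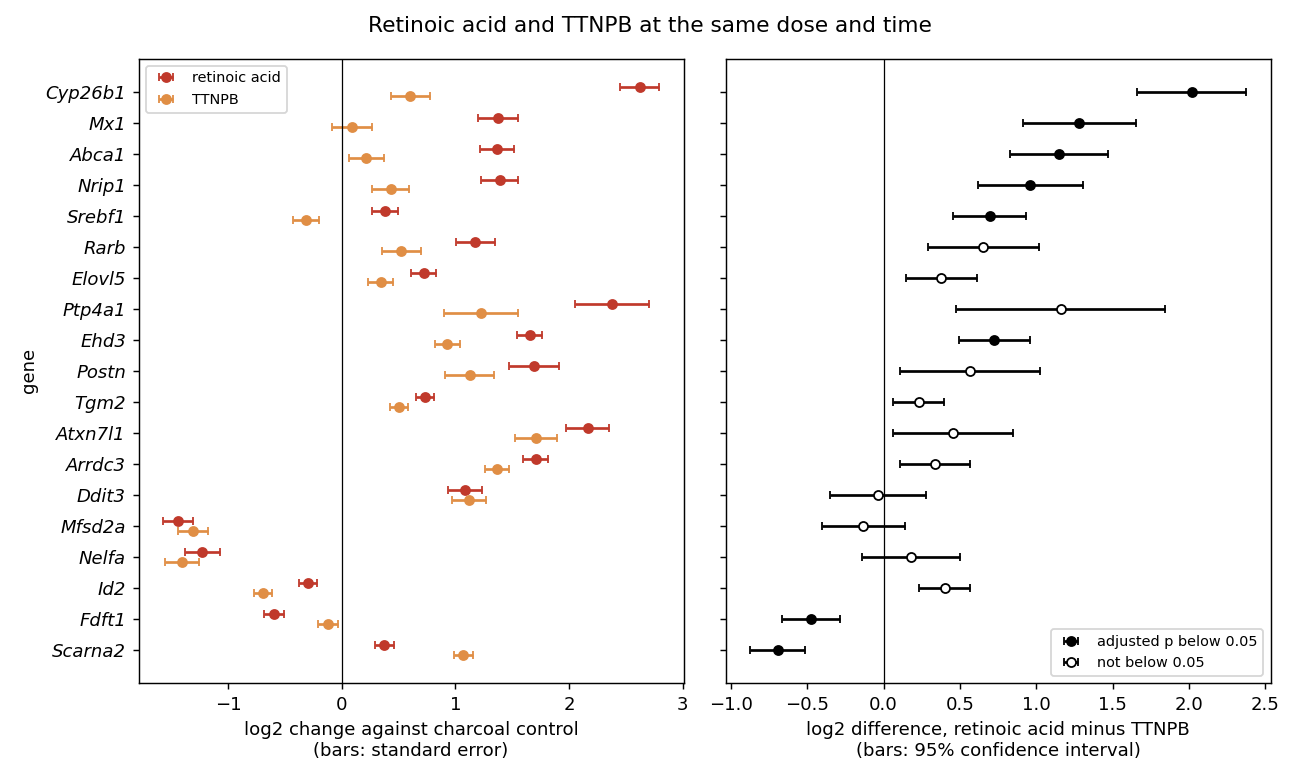
Left, log2 changes against the charcoal control with retinoic acid and TTNPB (bars, SE) for 19 genes; right, the log2 difference between the compounds with its 95% confidence interval, filled where the adjusted p is below 0.05. Cyp26b1 shows the largest difference of these genes, 2.02 (1.66 to 2.37), while the interval of Ddit3 spans 0.

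GW1516 raised Cpt1a, which encodes the carnitine palmitoyltransferase that admits fatty acids to mitochondrial oxidation, 1.64-fold, from 7.12 ± 0.10 to 7.83 ± 0.08 (SD, n = 3 each; log2 change 0.71 ± 0.10 SE, adjusted p = 0.00116). Cpt1a (probe set 17355915, Entrez 12894) lies on chromosome 19 from 3322326 to 3385735. The mitochondrial carrier gene Slc25a34 rose 2.69-fold (adjusted p = 0.00523), Uprt 3.04-fold, Postn 2.92-fold, Arrdc3 2.67-fold and Slc7a11 2.48-fold. Larger changes than that of Cpt1a were also seen for the ribosomal protein gene Rps23 (log2 change 1.67, adjusted p = 0.0202) and Atxn7l1 (1.53). Large falls were those of Rnu3a (log2 change -2.40), Fem1a (-1.535), Mypop (-1.29) and Fam207a (-1.28). Of 22 PPAR targets 3 rose and none fell, the same numbers as when adjusted over the list alone, namely Cpt1a, Klf10 (0.61) and the acyl-CoA dehydrogenase gene Acadl (0.45). The list shifted upward (adjusted p = 0.0172, and adjusted p = 0.139 with an estimated correlation). Of 20 fatty acid oxidation genes 3 rose, also 3 when adjusted over the list alone, with Acadm (0.62, adjusted p = 0.0497) beside Cpt1a and Acadl. That list shifted upward (adjusted p = 0.0338, and adjusted p = 0.361 with an estimated correlation). Of 19 RAR targets 2 rose (3 when adjusted over the list alone), Rara by 0.63 (adjusted p = 0.0424) and Tgm2 by 0.38 (adjusted p = 0.0154), and the list did not pass (adjusted p = 0.522). Plin2 (0.35, adjusted p = 0.291), Pdpk1 (0.40, adjusted p = 0.298) and Fabp5 (0.00, adjusted p = 0.998) did not pass, and Pdk4 and Angptl4 were under background with GW1516.

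Of the 24 cell cycle genes, 8 fell and 2 rose with GW1516 (10 and 4 when adjusted over the list alone). Cdc6 fell by 0.90, the replication licensing gene Mcm3 by 0.75 and the mitotic kinase gene Aurkb by 0.67, while Top2a rose by 0.65 (adjusted p = 0.000145 for the list, and adjusted p = 0.196 with an estimated correlation). In the list of fatty acid synthesis genes and LXR targets, Abca1 (0.90) and Scd1 (0.34) rose and the fatty acid synthase gene Fasn fell (-0.34), with 5 rises and 1 fall when adjusted over the list alone (adjusted p = 0.0338, and adjusted p = 0.293 with an estimated correlation). Of 20 genes of apoptosis and growth arrest 3 rose (4 when adjusted over the list alone), Trp53inp1 by 0.80, Bcl2 by 0.65 and Cdkn1b by 0.65 (adjusted p = 0.0338, and adjusted p = 0.293 with an estimated correlation). Of 18 genes of hypoxia and glycolysis 2 rose (3 when adjusted over the list alone), Bnip3 by 0.62 and P4ha1 by 0.53 (adjusted p = 0.0172, and adjusted p = 0.196 with an estimated correlation).

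GW1516 changed 570 genes, with 419 rises and 151 falls. The count was 3 when the fit held only these 6 arrays (adjusted p = 0.197 for Cpt1a, 0.167 for Slc25a34, 0.211 for Klf10 and 0.335 for Tgm2), 198 and 292 without control replicates 2 and 1, and 711 without GW1516 replicate 3, and 2 of 43 named genes (Arrdc3 and Uprt) passed under every setting chosen beforehand. The list of PPAR targets had adjusted p = 0.12 and 0.142 without GW1516 replicates 1 and 2, and the other lists named for GW1516, except the cell cycle list, lost their calls there as well and without control replicate 1 or 2 (0.245 for fatty acid oxidation without replicate 2), and without dim genes (0.0966 for oxidation, apoptosis and hypoxia and 0.0745 for fatty acid synthesis).

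Set directly against GW1516, retinoic acid gave higher Cyp26b1 (log2 difference 2.61), the transporter gene Slc6a13 (1.44), Snai1 (1.25), Mx1 (1.20), Rarb (1.02 ± 0.17 SE, adjusted p = 0.00978) and Nrip1 (0.96). Slc25a34 (log2 difference -1.48), Rhob (-0.74), Cpt1a (-0.72 ± 0.10, adjusted p = 0.00181), H1f5 (-0.69) and Egln3 (-0.59) were higher with GW1516. RAR targets were higher with retinoic acid (3 of 19 passed, 4 when adjusted over the list alone; adjusted p = 0.00578, and adjusted p = 0.102 with an estimated correlation). Cholesterol synthesis genes were lower (1 of 18 passed, also 1 when adjusted over the list alone; adjusted p = 0.00578, and adjusted p = 0.273 with an estimated correlation). Serum response genes were lower (none of 23 passed, 5 when adjusted over the list alone; adjusted p = 0.00791, and adjusted p = 0.273 with an estimated correlation). Fatty acid synthesis genes and LXR targets were higher (none of 17 passed, 4 when adjusted over the list alone; adjusted p = 0.0166, and adjusted p = 0.273 with an estimated correlation). In all 78 genes differed, 63 of them higher with retinoic acid, and 2 on these 6 arrays alone, where Rarb had an adjusted p of 0.288 and Cpt1a of 0.126. Without GW1516 replicate 1 the lists lost their calls (adjusted p = 0.169 for RAR targets, 0.208 for cholesterol synthesis, 0.281 for serum response and 0.169 for fatty acid synthesis), the last 3 also without GW1516 replicate 2 (0.440, 0.422 and 0.130) and with fry (0.113, 0.113 and 0.0878), serum response without retinoic acid replicate 3 (0.120) and fatty acid synthesis without replicate 1 (0.0721), without dim genes (0.0866) and after quantile normalization (0.0611), and Rarb lost its call without retinoic acid replicate 1 (0.0665).

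TTNPB and GW1516 differed in 15 genes. Cpt1a (log2 difference -0.95 ± 0.10 SE, adjusted p = 0.000499), Slc25a34 (-1.53), Uprt (-0.94), Rhob (-0.72), Id2 (-0.54) and the mitochondrial carrier gene Slc25a42 (-0.53) were higher with GW1516, while the small RNA gene Scarna6 (0.82) and the tight junction gene Cldn3 (0.45) were higher with TTNPB. No list passed, though those of PPAR targets and serum response did after quantile normalization (adjusted p = 0.0454 and 0.0231). Without GW1516 replicate 3 these 2 lists (0.0109 and 9.35e-07) and those of apoptosis (0.0449), ER stress (0.0449) and NRF2 and AhR targets (0.0098) passed, PPAR targets also without dim genes (0.0206) and with fry (0.0255), and serum response without TTNPB replicate 3 (0.0105). On these 6 arrays alone limma called none of the 15, with 1114 genes at an unadjusted p below 0.05, and the count was 45 without GW1516 replicate 3 and 4 without TTNPB replicate 2.

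Many changes were shared by the 3 ligands. Retinoic acid and TTNPB moved 227 genes in the same direction, retinoic acid and GW1516 403 and TTNPB and GW1516 147, with 142 genes (92 rises and 50 falls) common to all 3. Among them Arrdc3 rose by 1.71, 1.37 and 1.41, Atxn7l1 by 2.16, 1.71 and 1.53 and Ddit3 by 1.08, 1.12 and 1.09 with retinoic acid, TTNPB and GW1516. Mfsd2a fell by 1.44, 1.31 and 1.07, and Cdc6 by 0.90, 0.85 and 0.90. The comparisons share the 3 control arrays, which by itself correlates them. The covariance of effects across genes was 0.0395 for retinoic acid and TTNPB, 0.0427 for retinoic acid and GW1516 and 0.0303 for TTNPB and GW1516. When deviations of whole arrays were dealt out at random 100 times, it had means of 0.018, 0.020 and 0.018. The highest values in these draws, 0.0662, 0.0707 and 0.0556, were above those observed.

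Contrasts that share no array with the choice of genes gave a partial check. They cannot exclude a trend in array quality that runs across groups, which was not tested here. The median of the receptor genes was 0.703 to 0.740 with retinoic acid, 0.721 to 0.836 with TTNPB and 0.747 to 0.861 in charcoal controls. The 419 genes raised by GW1516 were on average 0.25 higher with retinoic acid than with TTNPB (adjusted p = 5.04e-40, and adjusted p = 0.00982 with an estimated correlation). The 151 lowered by GW1516 had a mean of -0.06 there (adjusted p = 0.00239, adjusted p = 0.480 with an estimated correlation and 0.0729 without charcoal control replicate 2). The 137 raised by TTNPB were 0.22 higher with retinoic acid than with GW1516, and the 142 lowered were at -0.17 (adjusted p = 0.00982 with an estimated correlation for each). Under palmitate, the genes raised by GW1516 had a mean of -0.02 (adjusted p = 0.449) and those lowered of 0.01 (adjusted p = 0.915). Those raised by TTNPB had a mean of -0.002 (adjusted p = 0.915), and those lowered by TTNPB of -0.06 (adjusted p = 0.00253, and adjusted p = 0.361 with an estimated correlation). That last shift was lost without charcoal control replicate 3, TTNPB replicate 2 or palmitate replicate 2 (adjusted p = 0.0709, 0.12 and 0.0932).

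Palmitate, against the full-medium control, lowered Acaca, which encodes the acetyl-CoA carboxylase that commits carbon to fatty acid synthesis, 1.78-fold, from 5.81 ± 0.13 to 4.99 ± 0.14 (SD, n = 3 each; log2 change -0.83 ± 0.11 SE, adjusted p = 0.00106). Acaca (probe set 17254395, Entrez 107476) lies on chromosome 11 from 84129635 to 84401651. Scd1, which encodes the desaturase that acts on saturated fatty acids, fell 1.36-fold (log2 change -0.44 ± 0.08, adjusted p = 0.0124). These were 2 of 17 members of the list of fatty acid synthesis and LXR targets, with 5 falls when adjusted over the list alone, and the list shifted downward (adjusted p = 0.000182, and adjusted p = 0.0848 with an estimated correlation). Other falls were those of Ube3c (log2 change -1.12), Sptbn1, which encodes a spectrin (-1.10), and Dock8 (-0.91). Rises included Rnu3a (1.51, adjusted p = 0.0487), Scarna17 (1.35), the proteasome gene Psmc6 (1.14) and Anxa1, which encodes annexin A1 (0.91). Smaller rises were those of the translation factor gene Eif3e (0.88), Gpx8 (0.80) and the receptor gene Rxrb (0.66). Rnu3a fell with retinoic acid, TTNPB and GW1516 (log2 changes -1.86, -2.04 and -2.40).

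Of 19 genes of ER stress 1 rose with palmitate (2 when adjusted over the list alone), the chaperone gene Hsp90b1 by 0.35, and the list shifted upward (adjusted p = 0.0449, and adjusted p = 0.715 with an estimated correlation). None of the 18 cholesterol synthesis genes passed, also when adjusted over the list alone, but the list shifted downward (adjusted p = 0.0449, and adjusted p = 0.715 with an estimated correlation). RAR targets (adjusted p = 0.971) and PPAR targets (adjusted p = 0.971) did not shift, and no member of either passed over all genes (1 of each rose when adjusted over the list alone). Fabp5 had a log2 change of -0.04 ± 0.18 (SE), Ppard of 0.13 ± 0.15, Rara of -0.04 ± 0.16 and Plin2 of 0.38 ± 0.16 (adjusted p = 0.539), while Rarb, Cyp26a1, Dhrs3, Crabp2, Pdk4 and Angptl4 were under background in full medium.

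Palmitate changed 151 genes, 32 upward and 119 downward, but 1 on the 6 full-medium arrays alone, where Acaca and Scd1 both had an adjusted p of 0.0772. The count was 62 without control replicate 3, 67 without control replicate 2 and 95 without palmitate replicate 2, with Scd1 at an adjusted p of 0.0876 and 0.0502 without control replicates 2 and 3 and 0.069 without palmitate replicate 1, and the lists of ER stress and cholesterol synthesis each lost theirs when any 1 of 4 arrays was left out, on the 6 arrays alone (0.0824 and 0.107) and with fry (0.348 and 0.365), the latter list also after quantile normalization (mean -0.06, 0.720) and without dim genes (0.429).

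The palmitate effect was also set against the retinoic acid effect, as an interaction across sera, at unequal doses (10 and 1 µM) and the same time. It differed for 568 genes, 459 of them lower with palmitate. Lower and higher here compare the change with palmitate to the change with retinoic acid, so a lower gene need not fall with palmitate. Cyp26b1 (difference of log2 changes -2.58), Elovl5 (-1.08), Acaca (-0.99), Elovl6 (-0.97) and Cdkn1b (-0.86) were lower, and Rxrb (0.95) and Mcm5 (0.62) higher. Rnu3a was also higher, with a log2 change of 1.51 with palmitate and of -1.86 with retinoic acid. Nrip1 (-1.58), Rarb (-1.12) and Abca1 (-1.44) were lower as well, but Nrip1 and Rarb were under background in both full-medium groups and Abca1 stood at 0.75 and 0.82 there, beside backgrounds of 0.63 and 0.59, so that for them the difference rests on retinoic acid. With palmitate itself, Cyp26b1 changed by 0.04 and Cdkn1b by -0.16 (adjusted p = 0.951), so their differences rest mainly on retinoic acid too. Elovl5 (-0.36, adjusted p = 0.234), Elovl6 (-0.39, adjusted p = 0.355) and Mcm5 (0.13, adjusted p = 0.684) did not pass with palmitate itself. Fatty acid synthesis genes and LXR targets were lower (5 of 17 passed, 9 when adjusted over the list alone; adjusted p = 2.44e-07, and adjusted p = 0.0140 with an estimated correlation). RAR targets (3 of 19 lower, 5 when adjusted over the list alone; adjusted p = 0.0166, and adjusted p = 0.127 with an estimated correlation) and genes of apoptosis and growth arrest (3 of 20 lower, and 7 lower with 1 higher when adjusted over the list alone; adjusted p = 0.00654, and adjusted p = 0.152 with an estimated correlation) were lower too. The count was 306 without retinoic acid replicate 2 and 321 without replicate 1, 361 and 371 without full-medium control replicates 2 and 3 and 373 without charcoal control replicate 2, and the apoptosis list had an adjusted p of 0.054 after quantile normalization and 0.105 without dim genes.

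Against the GW1516 effect, the palmitate effect differed for 280 genes, 234 of them lower. Cpt1a (difference -0.87 ± 0.14 SE, adjusted p = 0.00547), Klf10 (-0.75), Scd1 (-0.79), Acaca (-0.89) and Abca1 (-0.98) were lower with palmitate, Abca1 again with full-medium values close to background. Scd1 and Acaca fell with palmitate itself, while Cpt1a (-0.16, adjusted p = 0.948) and Klf10 (-0.14) did not pass there. Fatty acid synthesis genes and LXR targets (5 of 17 lower, 6 when adjusted over the list alone; adjusted p = 7.64e-05, and adjusted p = 0.0648 with an estimated correlation) and genes of apoptosis and growth arrest (3 of 20 lower, and 5 lower with 1 higher when adjusted over the list alone; adjusted p = 0.00622, and adjusted p = 0.149 with an estimated correlation) were lower. On the 12 arrays of these groups alone 8 genes passed, and Cpt1a and Scd1 had an adjusted p of 0.0651. The count was 125, 129, 134, 153, 166 and 177 without full-medium control replicate 2, charcoal control replicate 2, full-medium control replicate 3, charcoal control replicate 1, palmitate replicate 2 and charcoal control replicate 3, and 611 without GW1516 replicate 3, and the apoptosis list had an adjusted p of 0.0918 without GW1516 replicate 2.

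**Figure D4:**
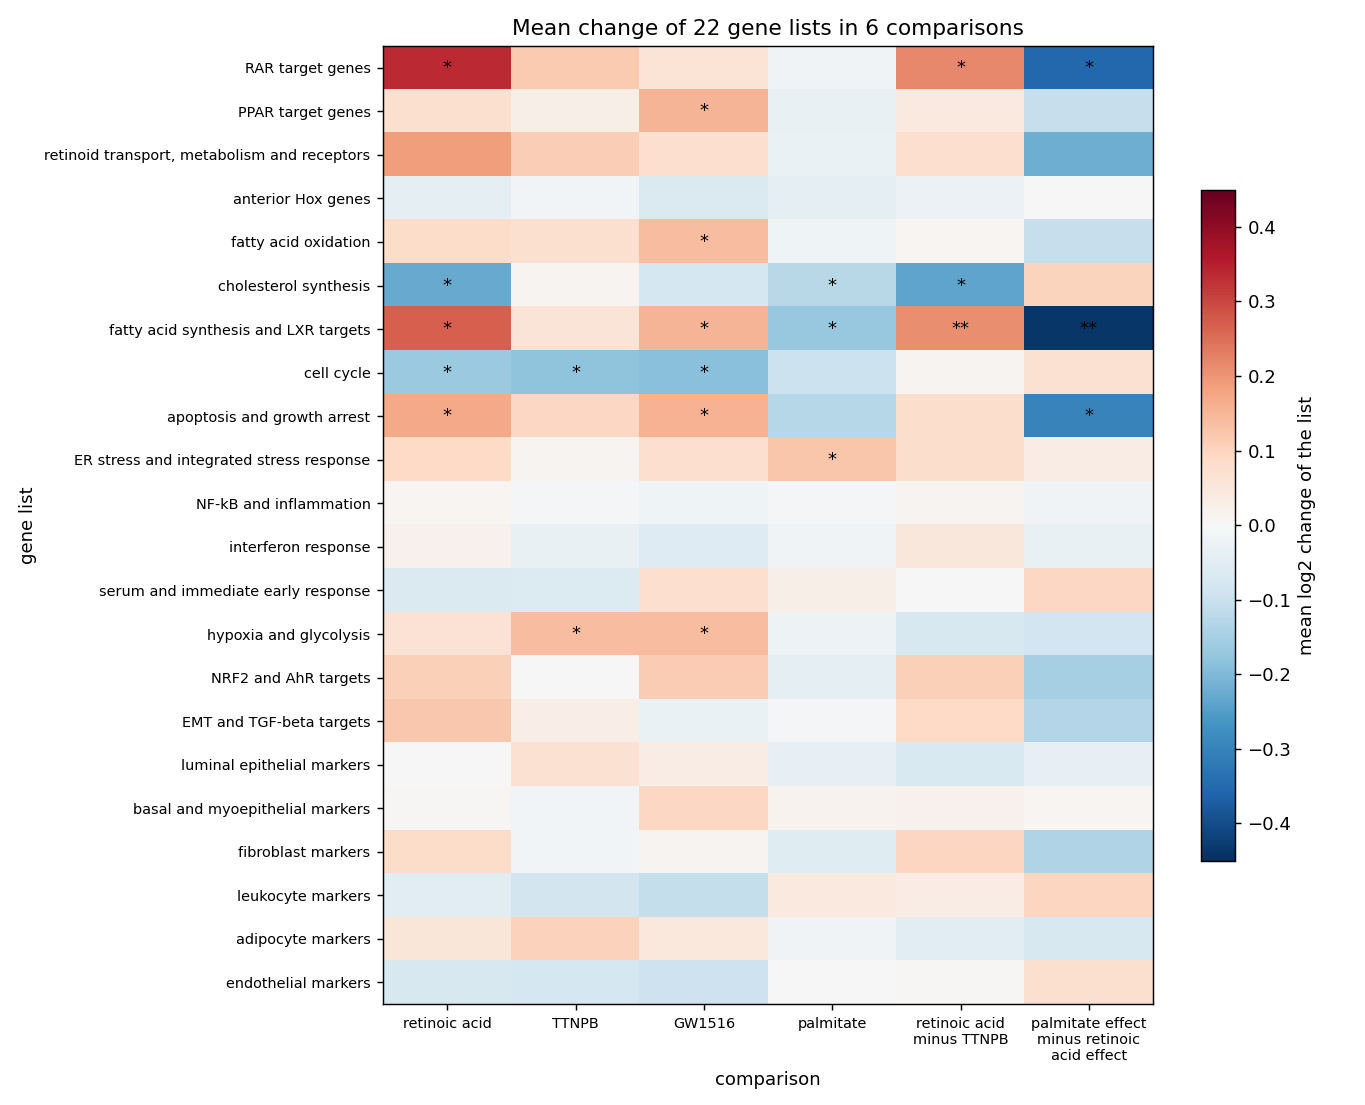
Mean log2 change of the genes of 22 lists in 6 comparisons; 1 star marks an adjusted p below 0.05 with the preset correlation and a pair of stars also with an estimated correlation. Fatty acid synthesis genes and LXR targets have the pair of stars for retinoic acid minus TTNPB (adjusted p = 0.0387) and for the palmitate effect minus the retinoic acid effect (adjusted p = 0.0140).

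The full-medium and charcoal controls differed in 20741 of 22180 genes, 20692 of them lower in full medium, with a median change of -0.66. After quantile normalization 7613 genes differed, and 56.7% of these were higher in full medium. The largest falls were those of Sh3bgrl (-6.89), Cops2 (-6.71) and Cd2ap (-6.34), and the largest rises those of Rpl34 (1.13), Adssl1 (1.02) and Tagln2 (0.89), and these kept their direction after quantile normalization. Cyp26b1 had a log2 difference of -1.37 and Fabp5 of -1.68 as deposited, and of 0.73 and 0.37 after quantile normalization. Of the lists, the cell cycle genes were lower beyond the median of other genes (24 of 24 lower, also when adjusted over the list alone; adjusted p = 0.0103, and adjusted p = 0.810 with an estimated correlation), with an adjusted p of 0.265 after quantile normalization.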

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

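The tests of control cultures handled apart, of the serum as a cause, of array deviations dealt out at random and of held-out arrays were chosen after the results were seen. Probe sets that carry no gene symbol or several were outside the comparisons and were tested by limma in the same way, as a signal in data the comparisons did not use. Of 17824 such probe sets, retinoic acid changed 25 (17 upward, 8 downward), TTNPB 4 (2 upward, 2 downward), GW1516 8 (6 upward, 2 downward) and palmitate 3 (all downward).

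The first pattern is that 142 genes moved the same way with retinoic acid, TTNPB and GW1516. In the test set beforehand for noise of the shared controls, 142 genes stood against at most 0 in 100 simulations of unchanged groups. That test was set aside, because with every gene unchanged almost nothing is called, so its outcome was nearly fixed. Noise of single control arrays cannot be told apart from a shared response. Genes chosen on 2 replicates of each group had mean log2 changes of 1.11 (rises, 95% interval -0.31 to 2.53) and -0.69 (falls, -1.03 to -0.34) on the replicate held out, each choice with equal weight. However, 1 choice held only 3 rises and 3 falls and another 6 and 9, under the 10 set as a minimum. The choice with replicate 3 held out met it, with 109 rises and 62 falls. Their means went from 0.84 to 0.46 and from -0.66 to -0.53 on the held-out arrays, with 89.0% and 90.3% in the same direction. A handling step common to every treated culture would move these genes with palmitate too, but 77 of the rises that lay over background in full medium had a mean palmitate change of -0.005263 (95% interval -0.13 to 0.12), below 0.359, which is 50% of their mean with the weakest ligand. For 47 of the falls that mean was 0.0004614 (interval -0.11 to 0.12), against -0.32. Control cultures handled or processed apart from the treated ones cannot be told apart from a common ligand response, because the serum has no other control group. In 142 of 142 genes the 3 controls lay beyond all 9 treated arrays, but the choice of these genes makes that nearly certain. A response shared by RAR and PPARδ ligands is thus only a hypothesis.

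The second pattern is that palmitate calls were mostly falls (119 of 151). Without palmitate replicate 2, the array farthest from its group, 68.4% of 95 calls were falls, which argues against that array as the only cause. The share of falls and the number of calls were both lower than with all arrays, so the array may account for part of the surplus. The palmitate effect had a correlation of 0.0245 across 9714 genes with the gap that sets GW1516 replicate 3 apart. The median gap of 118 of the falls, -0.08, lay within the range of random genes (-0.25 to -0.03). These values argue against a trend like that of GW1516 replicate 3. Other shifts between the full-medium arrays were not tested as a cause of the surplus. Palmitate was refitted after quantile normalization and on arrays centred on their medians, with fewer calls on centred arrays. The share of falls in those fits was not weighed here. The upper quartile of all probe sets was 1.25 to 1.29 on palmitate arrays and 1.31 to 1.35 on their controls. Background was 0.63 and 0.59, with 9996 and 10512 genes above it. The surplus of falls may be a response to palmitate, which stays a hypothesis found and tested on the same data. With the 6 full-medium arrays alone only 1 gene passed, which limits both readings.

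The third pattern is that nearly every gene read lower on the full-medium arrays. Scaling alone would leave few differences after quantile normalization, but 34.3% of genes were still called. The serum alone would not move genes of unexpressed receptor families, yet the sets differed by 0.450 in the median log2 value of those genes. A technical difference between the sets together with an effect of the serum may be present, and the design, with 1 serum per set, gives no value that parts them.

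Each count of genes between 3 and 3 arrays was set beside the other splits of the same 6 arrays, and 10 splits are too few for a share under 0.05. Every other split mixes arrays of both groups, so any difference between the groups adds to its spread and lowers its count. The counts of the other splits are thus no measure of the calls to be had without an effect. In each of the 8 comparisons 1 of the 10 splits, the real one, gave as many genes. The real count and the highest of the other splits were 1174 and 0 for retinoic acid, 279 and 0 for TTNPB, 570 and 12 for GW1516, 151 and 1 for palmitate, and 20741 and 0 for the sera. They were 34 and 2 for retinoic acid against TTNPB, 78 and 2 for retinoic acid against GW1516, and 15 and 1 for TTNPB against GW1516.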

How the results depend on the processing

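The fits on arrays of the same serum and without both GW1516 replicate 3 and palmitate replicate 2 were chosen after the data were seen, and the other settings before. Of 205 alternative counts of changed genes, 105 stayed within 1.5 times the reported count and 100 did not. Fits with a robust prior, without a variance trend, with the mean of probe sets or with all probe sets kept every count within that range. Changes near background limit the comparisons across sera, and small changes are often missed, since 40.1% to 45.8% of simulated log2 changes of 0.5 were recovered. Of simulated GW1516 calls 27.0% were false when each array kept its own spread. Causes of the changes below were not tested unless the alternative itself (fewer arrays or a stricter threshold) gives them.

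On only the arrays of the groups compared, the counts were 1852 for retinoic acid, 498 for TTNPB, 3 for GW1516, 1 for palmitate, 249 for retinoic acid against TTNPB, 2 for retinoic acid against GW1516, 0 in limma for TTNPB against GW1516 (1114 at an unadjusted p below 0.05), and 982 and 8 for the palmitate effect against the effects of retinoic acid and GW1516. On arrays of the same serum they were 1 for palmitate (2221 at an unadjusted p below 0.05), 40 for retinoic acid against GW1516 and 7 for TTNPB against GW1516. Without both doubted arrays they were 365 for palmitate, 142 and 61 for retinoic acid and TTNPB against GW1516, and 1145 for the palmitate against the retinoic acid effect, with 491 against the GW1516 effect. The replicate number, which did not pair the arrays, gave 9 for TTNPB against GW1516 as a block.

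In the order of retinoic acid, TTNPB, GW1516 and palmitate, arrays centred on their medians gave (from TTNPB on) 101, 299 and 32, array weights 2014, 622, 1122 and 661, a fold of at least 1.5 gave 706, 164, 356 and 86, and an adjusted p below 0.01 gave 518, 93, 162 and 55. Dim genes left out gave 454, 872 and 228 for TTNPB, GW1516 and palmitate, and quantile normalization 487 for TTNPB. For the sera, the counts were 7613 with quantile normalization, 8790 with centred arrays, 11301 without dim genes and 13312 with a fold of 1.5. For retinoic acid against TTNPB they were 20 with centred arrays, 136 with array weights and 15 below 0.01. For retinoic acid against GW1516 they were 128 with quantile normalization, 32 centred, 195 weighted, 118 without dim genes and 30 below 0.01. For TTNPB against GW1516 they were 23 with quantile normalization, 6 centred, 66 weighted and 3 below 0.01. The palmitate against retinoic acid effect gave 322 centred, 1449 weighted and 192 below 0.01, and that against GW1516 gave 71 centred, 849 weighted, 425 without dim genes and 68 below 0.01.

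Leaving out 1 array at a time gave 583 to 932 for retinoic acid, 112 to 170 for TTNPB, 198 to 711 for GW1516, 62 to 141 for palmitate, 20122 to 20265 for the sera, 9 to 24 for retinoic acid against TTNPB, 27 to 136 for retinoic acid against GW1516, 4 to 45 for TTNPB against GW1516, and 306 to 496 and 125 to 611 for the palmitate effect against retinoic acid and GW1516. Retinoic acid against GW1516 gave 27, 28 and 40 without retinoic acid replicates 1, 2 and 3 and 122 and 136 without GW1516 replicates 1 and 2, and TTNPB against GW1516 gave 5 and 25 without GW1516 replicates 1 and 2 and 5 without TTNPB replicate 1. Of the 220 list tests, 29 lists shifted with the preset correlation, 2 with an estimated one and 51 with fry, and 21 to 37 without 1 array.

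Overlaps of calls were 103 to 167 for retinoic acid and TTNPB, 149 to 572 for retinoic acid and GW1516 and 59 to 323 for TTNPB and GW1516 without 1 array. Of these, 149, 226, 241 and 258 for retinoic acid and GW1516 came without control replicates 2 and 1 and retinoic acid replicates 2 and 1. An adjusted p below 0.01 gave 77, 118 and 34, and leaving out dim genes gave 373 and 247 for the pairs with TTNPB. Genes lowered by GW1516 had a mean of -0.0601 in retinoic acid against TTNPB (-0.0827 to -0.0367 without 1 array), with adjusted p = 0.480 with an estimated correlation and 0.372 with fry. Genes raised by GW1516 had a palmitate mean of -0.053 to 0.0165 without 1 array, past the threshold without full-medium control replicate 1 (adjusted p = 0.049). Genes lowered by TTNPB had a palmitate mean of -0.0616 (-0.0826 to -0.0305 without 1 array), with adjusted p = 0.36 with an estimated correlation and 0.128 with fry, and -0.031 (adjusted p = 0.103) for the 50 genes with the smallest p.

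Named genes that passed kept their call under every setting chosen beforehand in 40 of 61 cases for retinoic acid, 23 of 34 for TTNPB, 2 of 43 for GW1516, 1 of 24 for palmitate (Scarna17), 50 of 91 for the sera, 6 of 21 for retinoic acid against TTNPB, 1 of 27 for retinoic acid against GW1516 (Cyp26b1), 0 of 15 for TTNPB against GW1516, and 29 of 42 and 5 of 34 for the palmitate effect against retinoic acid and GW1516. Of single named genes, 26 values turned sign, all in full against charcoal serum. Quantile normalization gave 0.41 for Aldh1a1, 0.48 for Btg2, 0.73 for Cyp26b1, 0.52 for Dusp1, 0.10 for Dusp5, 0.001389 for Etfa, 0.45 for Ets1, 0.0233 for Fabp3, 0.37 for Fabp5, 0.94 for Hilpda, 0.54 for Hmox1, 0.0195 for Hoxa4, 0.10 for Hoxa5, 0.88 for Irf1, 0.0004034 for Lif, 0.0002827 for Ncoa3, 0.58 for Nfkbia, 0.48 for Ppp1r15a, 0.23 for Psmb9, 0.25 for Rai1, 0.93 for Rarg and 0.0895 for Tnfaip2. The mean of probe sets gave -0.52 for Myl12a and -0.59 for Rps18, and all probe sets gave -1.60 and -1.94.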

Other observations

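The classes of small RNA, histone, ribosomal protein and splicing factor genes were chosen after the data were seen, and their p-values are unadjusted. Small nucleolar and Cajal body RNA genes (78 measured) had a median log2 change of -0.36 with retinoic acid (1 rose, 11 fell), 0.06 with TTNPB (2 rose, 2 fell) and -0.20 with GW1516 (2 rose, 6 fell). Retinoic acid lay below TTNPB by a median of -0.44 (camera p = 0.00765 with an estimated correlation), with 5 members lower on their own. Of 10 Srsf splicing factor genes, 2 fell with retinoic acid, 2 with TTNPB, 3 with GW1516 and none with palmitate. The class had medians of -0.20, -0.38, -0.24 and -0.12 there (camera p = 0.0301, 0.00068, 0.0557 and 0.0827 with an estimated correlation). Histone genes (48) had medians of -0.16, -0.08 and -0.11 with retinoic acid, TTNPB and GW1516 (camera p = 0.00261, 0.0229 and 0.0241 with an estimated correlation) and of 0.07 with palmitate (p = 0.017). Ribosomal protein genes (67) had medians of -0.05, -0.00123, -0.10 and 0.05 in these groups (camera p = 0.501, 0.955, 0.18 and 0.0551 with an estimated correlation).

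Some of the 50 falls common to the ligands are named here after their values were seen, with no test of what they share. With retinoic acid, TTNPB and GW1516, the ribosome assembly genes Bop1 (log2 changes -1.08, -0.79 and -0.76) and Nop56 (-0.51, -0.56 and -0.47), the elongation regulators Hexim1 (-1.07, -0.88 and -0.84) and Nelfa (-1.23, -1.41 and -0.87) and the splicing factor gene Srsf6 (-1.07, -0.90 and -0.70) fell.

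The cell type lists held few genes above background, so 5 of the 6 could hardly have shown a shift. In the charcoal control the genes above it were 1 of 8 endothelial, 1 of 7 adipocyte, 3 of 10 basal, 3 of 10 leukocyte and 3 of 11 fibroblast markers, against 9 of 15 luminal epithelial markers. The luminal list did not pass, with adjusted p = 0.968 for retinoic acid, 0.336 for TTNPB, 0.607 for GW1516 and 0.971 for palmitate.

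Of the pathway lists not described so far, anterior Hox, NF-kB and interferon genes likewise had most members under background (5 of 13, 7 of 20 and 7 of 19 above it in the charcoal control). The others did not pass with retinoic acid, with adjusted p = 0.148 for retinoid handling (0.016 with fry), 0.166 for fatty acid oxidation, 0.204 for PPAR targets (0.0434 on the 6 arrays alone), 0.551 for ER stress, 0.262 for serum response and EMT genes, 0.148 for hypoxia and glycolysis (0.0157 with fry) and 0.719 for NRF2 and AhR targets.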
